A study of Bifidobacterium breve with 9 samples.

How the data were processed

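Processed tables of 9 RNA-seq libraries were used, 1 per culture, 3 each from B. breve SW1107E on 2% lactose, 3SL or BMO. Per the labels' protocols, cells were grown anaerobically, RNA was stabilised at harvest and purified on Qiagen columns after mutanolysin and proteinase treatment, ribosomal RNA was depleted with RiboZero Plus and an Illumina prokaryotic library kit was used. Groups and replicate numbers were taken from the sample titles. Per the file headers, each table lists 1939 coding genes with their sequence, region, strand and coding length, and all of these lengths are multiples of 3. The deposited counts are total gene reads and unique gene reads per gene, not normalized. The deposited RPKM values are reads scaled by coding length and by a read total that the tables do not print, and the deposited TPM values sum to the same total in each library. The aligner, the counter, their versions and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Total and unique gene reads differed by at most 15 reads in a library.

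The total gene reads were tested. TPM was not used. RPKM was used with reads and length to compute the read total that it implies, 9072654 to 12159832 per library, and so the share of reads in listed genes. Gene reads per library were 229947 to 1744798. Before TMM scaling, 3 reads, the limit that a count of 0 allows, correspond to 1.72 to 13.0 CPM. Other CPM values given here are TMM-scaled. Counting intervals and such limits cover counting error only. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom of their counts was 4.16 to 1116.

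Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, by group), which left 1775 and removed 164. Counts were scaled by TMM, and 1 model with the group as its term was fitted to all 9 libraries with robust quasi-likelihood dispersions in R 4.3.3. The TMM factor was 0.277 in lactose replicate 3 and 0.911 to 1.46 in the other libraries, so that the levels of most genes in that library depend on the scaling. Contrasts were 3SL against lactose, BMO against lactose and 3SL against BMO, two-sided, with Benjamini-Hochberg adjustment at 0.05. Log2 CPM used a prior count of 2. The SE of a log2 fold change was its absolute value over the square root of the quasi-likelihood F statistic, not a fitted SE. The confidence intervals of log2 fold changes rest on this SE. The common biological coefficient of variation was 0.585.

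Gene lists by product and symbol had been fixed before the data were examined, but they could not be applied: 0 of the 1939 identifiers matched the reference table used here, that of another assembly of the species (ASM102517v1), and names were not guessed. In their place, after seeing the data, runs of neighbouring genes on one strand, with gaps of at most 50 bp and at least 3 tested genes, were tested with fry of limma 3.58.1, which asks whether the genes of a run move one way on balance; there were 95 runs with 352 genes. Camera, which compares a run with other genes, was computed with a preset and an estimated correlation. The rule for named genes fixed beforehand required an adjusted p under 0.05 and named none. Instead, the 2 largest positive and 2 largest negative log2 fold changes were taken per comparison among genes with non-overlapping groups and a mean log2 CPM of at least 4, a rule chosen after the values were seen. Stretches described by position were also chosen after their values were seen.

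The replicate numbers were checked as possible pairs by correlating the deviations of same-numbered libraries from their group means. The correlations were 0.486, 0.229 and 0.103 between 3SL and BMO, all over the 0.1 used as a limit, so these numbers were treated as possible pairs. This does not show that the cultures were paired. A fit with the replicate number as a block gave 0 genes and 0 runs for that comparison, as did the fit without it.

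The tests were tried on simulated data: counts for the 1775 genes from the observed means, library sizes and dispersions, with 50 genes changed by each of the folds given here. For 3SL against lactose, 6% of genes changed 2-fold, 22% changed 4-fold, 66% changed 8-fold and 94% changed 16-fold were recovered; for BMO against lactose the shares were 4%, 34%, 72% and 92%. Simulated without lactose replicate 3, the shares were 16%, 70%, 100% and 100% for 3SL against lactose and 6%, 60%, 92% and 100% for BMO against lactose. Unchanged groups were also simulated 20 times against the lactose libraries, with independent libraries and, added after seeing the data, with correlated deviations of same-numbered 3SL and BMO libraries; the simulated correlations were 0.364, 0.236 and 0.165. Fry recovered 10 of 10 runs changed 4-fold in 3SL against lactose. The simulated genes were drawn independently, whereas fold changes of neighbours within runs correlated at r = 0.83 in the data. This recovery therefore does not give the power or error rate of fry on the real runs. Alternatives were DESeq2 1.42.0, limma-voom, RLE and library-size scaling, other count filters, the replicate block, fits of the 6 compared libraries, leaving out each library, and, added after seeing the data, leaving out lactose replicate 3 and BMO replicate 1 together, and other definitions and tests of runs. All listed features are coding genes, so the planned removal of structural RNA had nothing to remove.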

Results

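Bifidobacterium breve SW1107E, an anaerobic gut bacterium, was grown in a basal medium with 1 of 3 carbon sources at 2%: lactose, 3SL or BMO. The label 3SL is the usual short form of 3'-sialyllactose, which is lactose carrying a sialic acid, and BMO is used here as the sample titles give it. The design text writes it as 2'-BMO, so which sugar or mixture this group received is not certain. RNA was taken at the middle of the growth phase, depleted of ribosomal RNA and sequenced from 3 cultures per carbon source, described as biological replicates, which gave 9 libraries and 3 comparisons. The question addressed by the design is which genes differ in expression between the carbon sources, with lactose as the reference sugar. Each library was counted over the same 1939 coding genes of a draft genome in 22 sequences. The gene identifiers are not paired with names, so genes and neighbouring genes are given by sequence number, start and end in that assembly, all of them coding regions.

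The summed gene reads were 1239862, 1744798 and 792894 in the lactose libraries, 510003, 243815 and 316718 in the 3SL libraries and 849165, 407678 and 229947 in the BMO libraries. These reads made up 10.9% ± 4.54 (SD, n = 3) of the read total implied by the RPKM values on lactose, 3.34% ± 1.57 on 3SL and 4.79% ± 2.67 on BMO. The share was lower in every 3SL library than in every lactose library, with p = 0.1 in a two-sided exact permutation test, which is the smallest p that 3 against 3 libraries can give. The corresponding exact permutation p was 0.2 for BMO against lactose and 0.6 for 3SL against BMO. In lactose replicate 3, the gene on sequence 1 from 394217 to 394720 took 29.1% of the gene reads, and the 5 most abundant genes together took 69.6%. The 5 most abundant genes took 7.62% and 8.27% in the other lactose libraries. Lactose replicates 1 and 2 correlated across genes with r = 0.95, whereas lactose replicate 3 correlated with them at r = 0.51 and 0.46 and with the 3SL libraries at r = 0.77 to 0.79. BMO replicate 1 correlated at r = 0.84 and 0.70 with BMO replicates 2 and 3, at 0.82 and 0.79 with lactose replicates 1 and 2 and at 0.75 to 0.80 with the 3SL libraries. Genes are not independent replicates in these correlations.

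**Figure D1:**
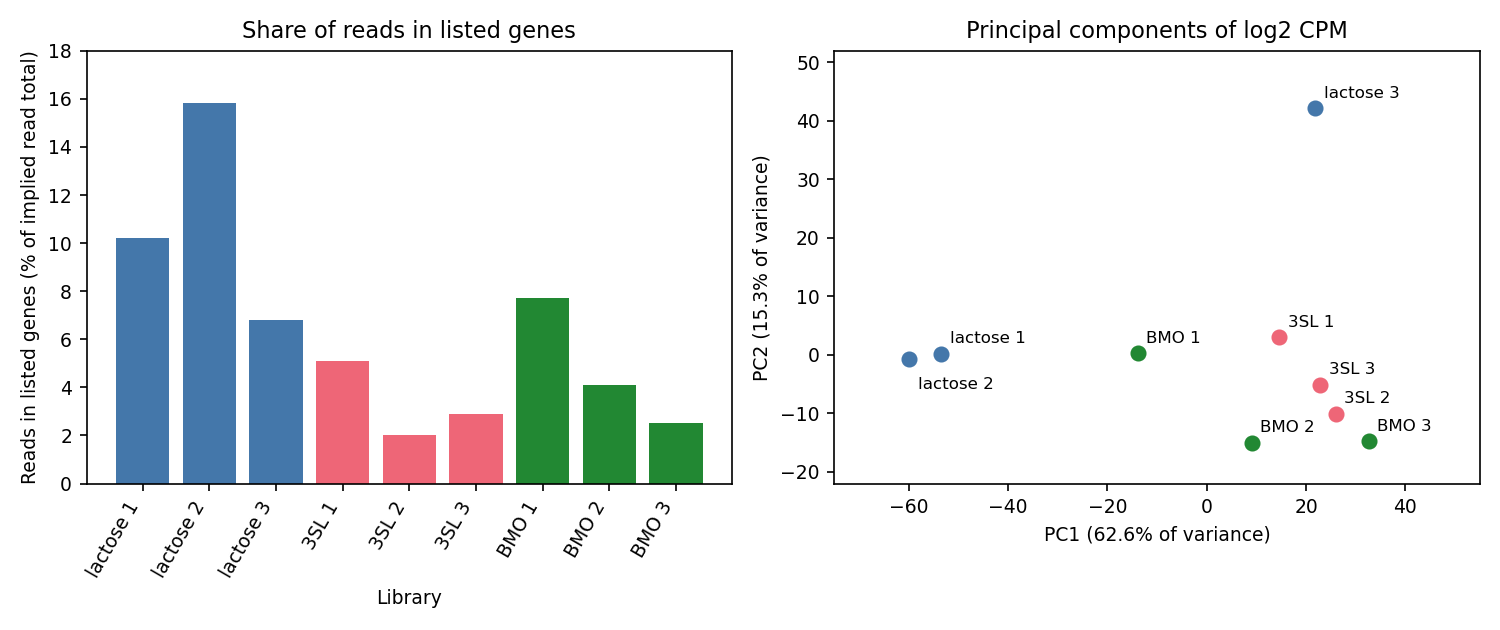
Left, bars give the share of the implied read total that fell in listed genes (%) for each of the 9 libraries; right, points give the libraries on the first and second principal components of log2 CPM, coloured by carbon source as in the bars. Gene-read shares ran from 2.02% to 15.8%, and lactose replicate 3 lies at 21.9 on the first component, apart from lactose replicates 1 and 2 at -53.5 and -59.9.

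In 3SL against lactose, 6 of 95 runs of neighbouring genes passed limma's fry test, 4 lower and 2 higher on 3SL. With limma's camera test, which compares a run with all other genes, none of them passed when the correlation between genes was estimated (adjusted p = 0.604 for each). A run is a stretch of at least 3 tested genes on one strand with gaps of at most 50 bp. On sequence 2, the run of 3 genes from 236531 to 240870 fell from a mean log2 CPM of 8.54 ± 0.24 (SD, n = 3) on lactose to 6.97 ± 0.05 on 3SL, with a median log2 fold change of -1.76 and an adjusted p of 0.0174 by fry. The run of 5 genes on sequence 4 from 125837 to 132632 fell from 5.98 ± 0.32 to 4.43 ± 0.42, with a median of -1.65 and the same adjusted p. On sequence 2, the run of 6 genes from 80675 to 84738 fell from 7.91 ± 0.41 to 6.10 ± 0.16, and the run of 3 genes from 150698 to 153195 fell from 8.30 ± 0.30 to 7.41 ± 0.24, each with an adjusted p of 0.0485 by fry. The run of 3 genes on sequence 2 from 209005 to 211913 rose from 7.41 ± 0.43 to 8.75 ± 0.16 (adjusted p = 0.0485 by fry), although 1 of its genes had a log2 fold change of -0.29. The run of 3 genes on sequence 1 from 159536 to 162581 rose from 7.54 ± 0.20 to 8.29 ± 0.15 (adjusted p = 0.0439 by fry). With TMM scaling, the mean level of every 3SL library lay on the same side of every lactose library in each of these 6 runs. The TMM factor was 0.277 in lactose replicate 3 and 1.04 to 1.40 in the 3SL libraries. With library-size scaling alone, lactose replicate 3 stands lower against them, so the separation of the lower runs need not hold. With that scaling, the 4 lower runs had adjusted p of 0.409 to 0.926 by fry. The median log2 fold change of all tested genes was -0.22 with TMM scaling and 0.14 with library-size scaling alone. Relative to it, the 6 run medians ran from -1.54 to 2.14 with TMM. With library-size scaling alone, the medians themselves ran from -1.49 to -0.60 in the 4 lower runs and were 1.13 and 2.52 in the higher ones. The calls depended on the scaling. By fry, 2 of the 6 runs passed with RLE scaling, those on sequence 2 from 236531 and on sequence 4 from 125837, with an adjusted p of 0.0506 for the others. Only 1 passed with library-size scaling alone, that on sequence 2 from 209005 (adjusted p = 0.0468 by fry). None of the 6 runs passed fry when lactose replicate 1, lactose replicate 2, 3SL replicate 1 or 3SL replicate 3 was left out. In those 4 fits the run medians kept their sign; that of the run on sequence 2 from 236531 was -1.87 to -1.55, and that of the run on sequence 2 from 209005 was 1.53 to 2.03. Of the 6, 2 passed without BMO replicate 2 and 3 without 3SL replicate 2, 4 passed without BMO replicate 3, and all 6 passed without lactose replicate 3 or without BMO replicate 1.

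**Figure D2:**
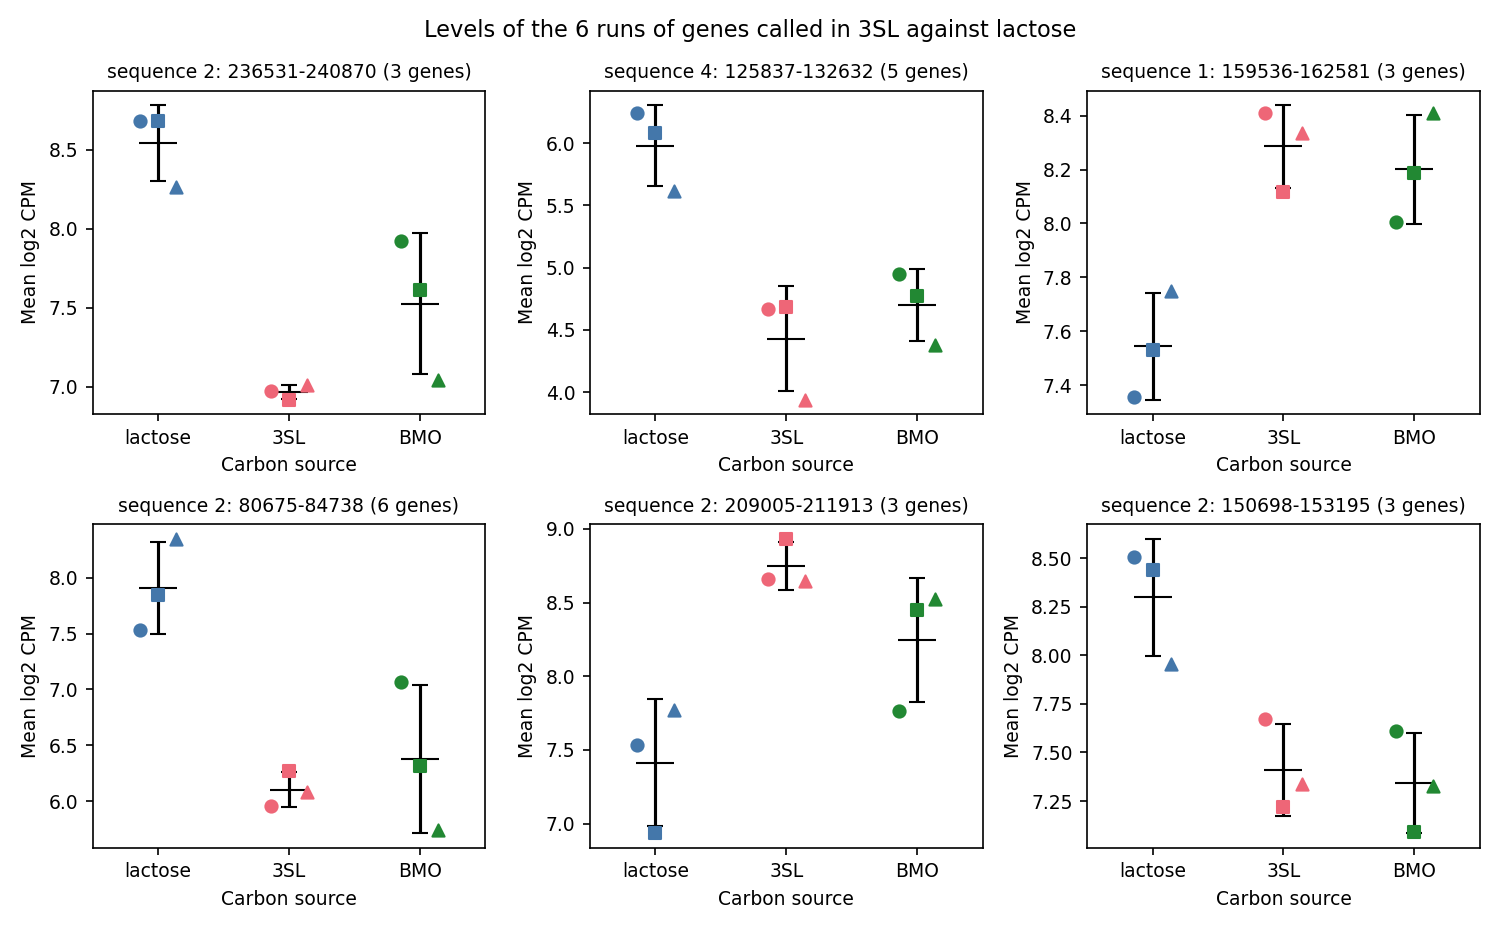
Each panel gives, for 1 of the 6 runs that passed in 3SL against lactose, the mean log2 CPM of its genes (vertical axis, which does not start at 0) in every library of each carbon source; circles, squares and triangles are replicates 1, 2 and 3, and the horizontal bar and whiskers are the mean and SD of 3 libraries. In the run on sequence 2 from 236531 to 240870 the 3SL libraries average 6.97 and the lactose libraries 8.54, with TMM scaling.

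Some runs that did not pass had larger median differences; the stretches named here were chosen after their values were seen. The run of 4 genes on sequence 7 from 23288 to 25447 had a median log2 fold change of 3.11 (adjusted p = 0.0853 by fry), with a mean log2 CPM of 3.76 ± 1.95 on lactose and 7.05 ± 0.63 on 3SL. The run of 4 genes on sequence 1 from 292381 to 295824 had a median of 2.45 (adjusted p = 0.0853 by fry), with 5.83 ± 1.63 on lactose and 8.85 ± 0.18 on 3SL. Among runs lower on 3SL, the median was -2.86 for 4 genes on sequence 1 from 236974 to 241809 (adjusted p = 0.0853 by fry), at 8.75 ± 1.45 on lactose and 6.17 ± 0.32 on 3SL. It was -2.87 for 3 genes on sequence 12 from 59415 to 62652 (adjusted p = 0.174 by fry), at 8.83 ± 1.96 on lactose and 6.81 ± 0.05 on 3SL, but this rested on lactose replicates 1 and 2, at 9.76 and 10.15, since lactose replicate 3, at 6.58, lay below every 3SL library. On the reverse strand of sequence 6, the 4 genes from 63412 to 68979 averaged 9.47 ± 1.39 on lactose, 7.01 ± 0.19 on 3SL and 7.24 ± 0.02 on BMO. Their log2 fold changes for 3SL against lactose ran from -3.81 to -1.98, with a lowest adjusted p of 0.0676 by edgeR. The lactose libraries stood at 7.88, 10.01 and 10.51 in this stretch.

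No single gene of the 1775 tested passed an adjusted p of 0.05 by edgeR's quasi-likelihood test in 3SL against lactose (lowest adjusted p = 0.0569), while 506 genes had an unadjusted p under 0.05, against 89 expected by chance. Another split of these libraries, with lactose replicates 1 and 2 and 3SL replicate 1 on one side, gave 421. That split keeps lactose replicates 1 and 2 opposite 3SL replicates 2 and 3. Splits with lactose replicates 1 and 2 on opposite sides gave 8 to 24. The splits therefore cannot tell a difference between the carbon sources from a departure of these 2 lactose libraries. Of the 506, found with TMM scaling, 183 were higher and 323 lower on 3SL. The fit with library-size scaling alone had its own list of 452 genes, 378 higher and 74 lower. DESeq2 called 284 genes and limma-voom 159. The gene with the largest positive fold change among genes with non-overlapping groups and a mean log2 CPM of at least 4, Ga0483833_01_148735_149289, had 77 reads over the 3SL libraries and 3 over the lactose libraries, a scaled ratio of 79.5 with a 95% counting interval of 26.2 to 394. All 3 of these lactose reads were in lactose replicate 1; without it, the level on 3SL was at least 45.6-fold higher than 3 reads over lactose replicates 2 and 3, which held 0. For Ga0483833_02_282749_283195 the log2 fold change was 4.63 ± 1.17 (SE), with an adjusted p of 0.0926 by edgeR. Without lactose replicate 3, in which it stood at 91.1 CPM against 5.80 and 6.48 in the other lactose libraries, it was 6.91 (adjusted p = 0.000415 by edgeR). For Ga0483833_03_74015_75283 and Ga0483833_01_242076_242771 the log2 fold changes were -3.97 ± 1.07 and -3.84 ± 1.15, with adjusted p of 0.0926 and 0.1 by edgeR. Without lactose replicate 3 they were -4.36 and -4.25, with adjusted p of 0.00158 and 0.00335 by edgeR. These genes were chosen after their values were seen, and lactose replicate 3 is a library unlike its group. The small adjusted p without it are therefore not independent support. In 507 genes, 242 higher and 265 lower on 3SL, every 3SL library lay on one side of every lactose library, which is 28.6% of the genes where chance gives 10%. With library-size scaling alone, 506 such genes were higher and 24 lower on 3SL. The median 95% confidence interval of a gene's log2 fold change was 1.31 to either side, or 2.48-fold. Without lactose replicate 3, edgeR called 848 genes, 462 higher and 386 lower on 3SL, and 66 of 96 runs passed fry, 23 higher and 43 lower. Without BMO replicate 1, edgeR called 5 genes.

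In BMO against lactose, 0 of 95 runs passed fry, 24 had an unadjusted p under 0.05, and camera called 15 with a preset correlation and 0 with an estimated one (lowest adjusted p = 0.609). The lowest adjusted p by fry, 0.0563, was reached by the run of 4 genes on sequence 14 from 18644 to 22388, at 7.54 ± 0.19 on lactose and 6.34 ± 0.35 on BMO, and by the run on sequence 4 from 125837 to 132632, at 5.98 ± 0.32 and 4.70 ± 0.29. The largest positive log2 fold changes among genes with non-overlapping groups and a mean log2 CPM of at least 4 lay in 2 stretches of sequence 3. The 3 genes from 253376 to 256411 had log2 fold changes of 4.21 to 6.65, and the stretch held 21192 reads in BMO replicate 1 against 100 and 78 in BMO replicates 2 and 3. Among these 3 genes, only that from 253376 to 254380 had non-overlapping groups. Without BMO replicate 1, the gene from 253376 to 254380 went from 6.65 to 2.37 (adjusted p = 0.165 by edgeR), and without lactose replicate 3 as well it was 4.13 (adjusted p = 8.09e-05 by edgeR). The 2 genes from 140895 to 143110 had log2 fold changes of 4.71 and 5.22, with 6895 reads in BMO replicate 1 against 106 and 76 reads in the other BMO libraries. Of these, only the gene from 140895 to 142178 had non-overlapping groups. Without BMO replicate 1, the gene from 140895 to 142178 went from 5.22 to 2.30 (adjusted p = 0.148 by edgeR), and without both libraries it was 3.69 (adjusted p = 0.000152 by edgeR). The genes on sequence 6 from 63412 to 68979 had log2 fold changes of -3.40 to -2.23, with a lowest adjusted p of 0.124 by edgeR. On sequence 2, the gene from 198803 to 198931 had a log2 fold change of -4.26 ± 0.93 (SE), with the same adjusted p of 0.124 by edgeR. Without lactose replicate 3 it was -3.17 (adjusted p = 0.00873 by edgeR). The named genes were chosen by their values, and the libraries left out were those unlike their groups. Small adjusted p in these fits are therefore not independent support.

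By edgeR, 0 of 1775 genes passed in BMO against lactose (lowest adjusted p = 0.110), and 285 had an unadjusted p under 0.05, of which 149 were higher and 136 lower on BMO. Of the 10 splits of these libraries, 3 had as many as 285, the real one included, and the highest other had 818. The fit with library-size scaling alone had its own list, 265 higher and 19 lower. DESeq2 called 88 genes and limma-voom 25. The groups did not overlap in 262 genes, or 14.8%, where chance gives 10%; 132 were higher and 130 lower on BMO, and 376 and 9 with library-size scaling alone. Without lactose replicate 3, edgeR called 497 genes, 339 higher and 158 lower on BMO, and 43 runs passed fry. Without BMO replicate 1, it called 2 genes and 9 runs passed.

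In 3SL against BMO, 0 of 95 runs passed fry (lowest adjusted p = 0.967), and 1 had an unadjusted p under 0.05. The run of 5 genes on sequence 5 from 107727 to 113238, at 6.69 ± 0.44 on 3SL and 5.67 ± 0.44 on BMO, passed camera with a preset correlation (adjusted p = 0.00592) but not with an estimated one (adjusted p = 0.906). The gene on sequence 5 from 197323 to 197718 had a log2 fold change of 2.97 ± 1.58 (SE), the gene on sequence 3 from 130904 to 131407 had 2.33 ± 0.67, and the gene on sequence 12 from 88394 to 90247 had -1.97 ± 0.80, each with an adjusted p of 0.999 by edgeR. The stretch on sequence 3 from 253376 to 256411 had log2 fold changes of -5.24 to -3.79. Without BMO replicate 1, its gene from 253376 to 254380 went from -5.24 to -0.90 (adjusted p = 0.998 by edgeR). By edgeR 0 genes passed, DESeq2 and limma-voom also called 0, and 42 genes had an unadjusted p under 0.05, against 89 expected by chance. That number was 182 of 1787 genes without lactose replicate 3, and 140 of 1701 with only the 6 libraries compared. The shortfall against chance thus depended on the libraries in the fit. Of the 42 genes, 11 were higher and 31 lower on 3SL. The fit with library-size scaling alone had its own list of 28 genes, 21 higher and 7 lower. The groups did not overlap in 215 genes, or 12.1%, where chance gives 10%; 118 were higher and 97 lower on 3SL, and 163 and 56 with library-size scaling alone. In data simulated for this comparison, 32% of genes changed 4-fold and 66% of genes changed 8-fold were recovered. Simulated without lactose replicate 3, which is outside this comparison but enters the estimate of the spread, the shares were 66% and 96%, and edgeR called 0 genes in that fit of the real counts as well.

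The stretch of 3 genes on the reverse strand of sequence 1 from 318643 to 322398 was abundant in 7 of the 9 libraries. It took 14.6% to 21.3% of the gene reads in the 3SL libraries, 5.92%, 16.4% and 23.2% in the BMO libraries and 36.9% in lactose replicate 3, but 0.312% and 0.143% in lactose replicates 1 and 2. Its mean log2 CPM was 12.02 ± 5.57 on lactose and 15.45 ± 0.50 on 3SL, while the fitted log2 fold changes ran from -1.63 to -0.88, so the mean of logs and the fitted values differed in sign. On the same strand of sequence 1, the stretch of 2 genes from 392860 to 394720 held 354 and 195 reads in lactose replicates 1 and 2, 249980 in lactose replicate 3, and 10021 to 16521 in the 3SL and BMO libraries.

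The fold changes of 3SL and of BMO against lactose shared the lactose libraries. By edgeR 0 genes were called in the same direction in both, DESeq2 called 78 and limma-voom 25, and 188 genes had non-overlapping groups in the same direction in both. Across the 1775 genes, which are not independent, the log2 fold changes correlated with r = 0.86, against 0.49 ± 0.03 (SD of 20 draws) in simulated unchanged groups with independent libraries and 0.63 ± 0.02 where same-numbered 3SL and BMO libraries deviated together about as observed. Their covariance was 1.32, against 0.269 and 0.343 in these simulations, which leaves differences of 1.05 and 0.973. The covariance depended on 1 library: it was 3.22 without lactose replicate 3, against 0.180 and 0.218 simulated. Without lactose replicate 3, 328 genes were called higher and 147 lower on both, where independent lists would share 87.6 and 34.1 and simulated unchanged groups shared 0.05 on average, or 0 with the paired deviations. The spread in these simulations was estimated without that library, so few shared calls were to be had by construction. A departure of lactose replicates 1 and 2 alone from the other libraries would also give shared calls, and neither baseline covers it. The simulated groups shared their lactose libraries too, so sharing as such is already in their values. Part of the excess may still come from a departure of the lactose libraries themselves, which at 3 could not be divided into 2 sets of at least 2.

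**Figure D3:**
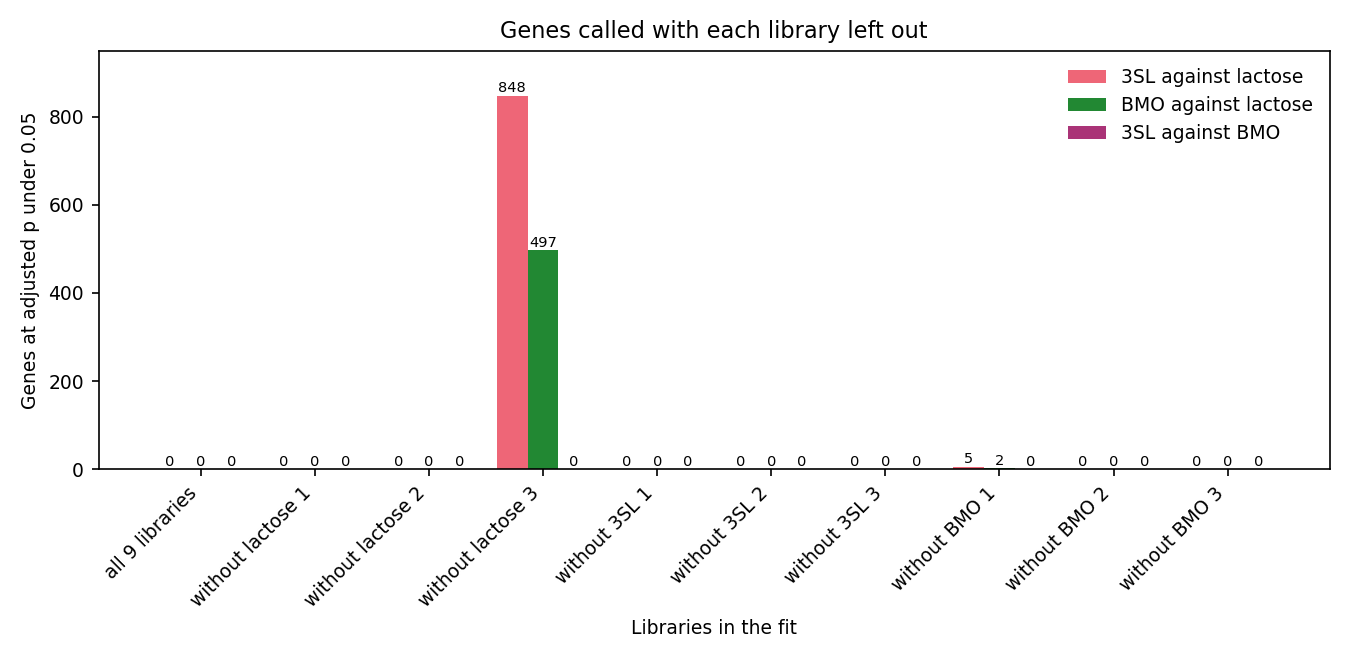
Bars give the number of genes at an adjusted p under 0.05 by edgeR for each of the 3 comparisons (vertical axis), in the fit of all 9 libraries and in fits with 1 library left out (horizontal axis). The counts were 848 and 497 without lactose replicate 3, 5 and 2 without BMO replicate 1, and 0 in the other fits.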

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

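The exchange of labels, the counts of splits for single genes and the use of runs were tests chosen after the results were seen. The share of the implied read total outside the listed genes was 96.7% on average on 3SL, at 94.9% to 98.0%, and every 3SL library lay above the highest lactose library, at 93.2%; on BMO it was 92.3% to 97.5%. What these reads are was not analysed here.

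Lactose replicate 3 lay apart from lactose replicates 1 and 2. Removing the 23 genes that took over 1% of any library left its mean r with them at 0.486, against 0.483 before. It stayed below its lowest r with a 3SL library, 0.729. The low r thus did not rest on the values of these 23 genes themselves. Their removal does not give back the reads they took from other genes, so it cannot decide on abundant genes as the cause. Thinning every library to 118550 reads left r between lactose replicates 1 and 2 above their mean r with lactose replicate 3 by 0.446 on average (lowest of 20 draws 0.440), which argues against depth. On 255 genes that part lactose replicates 1 and 2 from BMO replicates 2 and 3, scaled from 0 for the former to 1 for the latter, lactose replicate 3 had a median of 0.790, near the BMO libraries, but BMO replicate 1 had 0.549 (quartiles 0.394 and 0.718), above the 0.25 that an exchange of these labels was taken to require; lactose replicate 3 also correlated better with 3SL (0.77 to 0.79) than with BMO replicates 2 and 3 (0.73 each), and the stretch on sequence 6 from 63412 to 68979 followed the labels, at 10.51 in lactose replicate 3 and 7.23 in BMO replicate 1. Part of this runs against a plain exchange. However, lactose replicate 3 met its part of what an exchange was taken to require. BMO replicate 1 lay between the groups, and that stretch was chosen for a difference between them. With these 2 labels exchanged, lactose against BMO called 563 genes and 37 runs and parted 782 genes, against 0, 0 and 262 as labelled. An exchange therefore cannot be told apart from 2 cultures unlike their groups. A single wrong label, culture state and a library effect also stay open, with no biological explanation tested.

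Every 3SL library lay on one side of every lactose library at 507 genes, 242 higher and 265 lower on 3SL, against 178 by chance; with library-size scaling alone, 506 were higher and 24 lower. Thinned to 229732 reads, 528 genes were parted on average (506 to 545 over 20 draws), so they did not rest on unequal read totals. The abundant genes were left in, and the 5 most abundant took 69.6% of the gene reads in lactose replicate 3. Depth at the other genes was therefore not made equal, and this thinning cannot decide on it. The median rise of the 242 higher genes was 2.99 times the level of the 10th percentile of genes on 3SL (quartiles 1.69 and 6.57). These genes were picked as higher with TMM scaling, which favours large rises. The ratio of upper to lower quartile of reads per kb was 8.12 and 8.46 in lactose replicates 1 and 2. It was 4.65 in lactose replicate 3, 3.94 to 4.51 on 3SL and 4.91 to 5.86 on BMO. Reads spread evenly over the genome could also narrow this range, so they stay open as a cause. Removing a curve on coding length left 518 genes, 480 of them shared with the 507 in the same direction. The carbon source stays open as untested, as does anything that goes with the lower gene-read share of the 3SL libraries. Another split, lactose replicates 1 and 2 with 3SL replicate 1, parted 474 genes. That split keeps lactose replicates 1 and 2 opposite 3SL replicates 2 and 3. It cannot tell the carbon source from a departure of these 2 lactose libraries.

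With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. In 3SL against lactose the real split called 0 genes and the highest other 0, so 10 of 10 splits had as many. For runs the real split called 6 and the highest other 0, so 1 of 10. In BMO against lactose the real split called 0 genes and 0 runs, and the highest other 563 genes and 37 runs, with lactose replicates 1 and 2 and BMO replicate 1 on one side. That split parted 782 genes, against 262 for the real one, which points to a structure of the libraries that does not follow the groups. It is the split that exchanging the labels of lactose replicate 3 and BMO replicate 1 would give. In 3SL against BMO the real split and the highest other called 0 genes and 0 runs, also among the 4 splits that part as many same-numbered pairs, the real one included. Of genes with non-overlapping groups the real split had 215, the highest other of those 4 had 166, and the highest of the remaining splits 422.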

How the results depend on the processing

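The joint removal of libraries and all alternatives for runs were chosen after the data were seen. Genes called by edgeR, 0 in each comparison, were more numerous with other tools: DESeq2 called 284 in 3SL against lactose, 88 in BMO against lactose and 78 in the same direction in both, and limma-voom 159, 25 and 25. Library-size scaling alone gave 168, 66 and 59 genes, and 15 and 7 runs, all of these runs higher than on lactose, against 6 and 0. RLE scaling gave 2 and 3 runs. Of the 6 runs in 3SL against lactose, 2 passed with RLE scaling, both lower, 1 with library-size scaling alone, a higher one, 1 with the replicate block, a lower one, and 6 with each other count filter. Leaving out 1 library gave 0 to 848 genes in 3SL against lactose, 0 to 497 in BMO against lactose and 0 to 475 in both, and 0 to 66 and 0 to 43 runs, the highest each time without lactose replicate 3; without BMO replicate 1 there were 5, 2 and 2 genes and 10 and 9 runs. Leaving out both gave 973, 856 and 748 genes and 66 and 61 runs. The cause of these changes was not tested. The 6 libraries compared alone gave 10 runs in 3SL against lactose. Gaps of up to 100 bp gave 0 and 1 runs and of up to 200 bp 3 and 2. Camera with a preset correlation called 14, 15 and 1 runs, and with an estimated one 0, 0 and 0. The replicate block gave 79 genes and 1 run in 3SL against lactose, and 0 genes and 1 run in BMO against lactose. For these comparisons the libraries share only a number: deviations of same-numbered libraries correlated at 0.12, -0.12 and 0.09 between lactose and 3SL and at 0.40, 0.05 and 0.55 between lactose and BMO, and 6 of 9 libraries correlated best with their own number. The other filters, RLE scaling and the 6 libraries alone kept 0 genes, and 3SL against BMO gave 0 genes in every alternative run. Named genes, which were chosen for large fold changes, passed the threshold in 32 of 212 alternatives. The planned gene lists and the removal of structural RNA were not run, for want of gene names and of such rows. Depth limits low genes: before TMM scaling, 3 reads are 13.0 CPM in the smallest library. They are 3.78 CPM in lactose replicate 3, where TMM scaling raises this limit, as the factor was 0.277.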

Other observations

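The tests in this part on neighbours were fixed before their results were seen, and the other values were picked after they were seen. Neighbouring genes shared their fold changes in 3SL against lactose. Across 431 neighbour pairs within runs the log2 fold changes correlated at r = 0.83, against 0.18 across 495 neighbour pairs on opposite strands, a difference of 0.650 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Neighbours on one strand further apart than 50 bp, 718 pairs, had r = 0.54. Genes are not independent replicates, and the noise of a library is shared along a transcript as well as a response to the carbon source, so the difference of 0.650 is consistent with transcription of runs as units and says nothing of its cause.

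With TMM or RLE scaling, genes at least 8-fold above their level in each other library numbered 12 in lactose replicate 3, 5 in BMO replicate 1 and 0 in the other 7 libraries. With library-size scaling alone they numbered 0 in lactose replicate 3 and 5 in BMO replicate 1, so the 12 depend on the scaling factor of that library. The 5 genes of BMO replicate 1 lie in the 2 stretches of sequence 3 from 253376 to 256411 and from 140895 to 143110. Of the 12 genes of lactose replicate 3 with TMM scaling, 5 lie on sequence 1 between 380417 and 394720.

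Over the 6 3SL and BMO libraries, the deposited RPKM of the gene on sequence 1 from 318643 to 319656 had a coefficient of variation of 11.8%, the second lowest of 1775 genes, whose median was 80.0%. It held 9045 to 10791 reads in each of these libraries, while their summed gene reads ran from 229947 to 849165.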
